A study of Drosophila melanogaster with 2 samples.

How the data were processed

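Hi-C, which joins and sequences DNA fragments lying close together in the nucleus, was applied to wild-type male Drosophila melanogaster embryos collected 16 to 18 h after egg laying. Males were sorted by a green fluorescent reporter on the Y chromosome, and the labels give 2 replicates of this single group. The deposited tables hold 1 map with no column for either replicate, so the values are those of the replicates together. No difference between groups and no spread between replicates could be computed.

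Per the submitters' processing notes, Bowtie was used and the genome build was dm3; no version is given in the sources used here. The deposited tables give, for each pair of bins, an observed count of contacts and an expected count, per the file headers. The model behind the expected count of the authors is not given in the sources used here. As checked on the values, the expected count held no term for distance and no correction for the single X of males. A further count per bin in the deposited tables, whose meaning no header states, summed to 588684 at each bin size from 10 to 160 kb and was used only as a description. Tables with bins of 40, 80 and 160 kb covered the whole genome. Those of 20, 10 and 5 kb held contacts within an arm alone, and the 20 and 10 kb tables reached 20 and 10 Mb.

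The map held 50391732 contacts, each pair of bins counted once. The median count of bin pairs over 1 Mb apart on an arm was 13 at 40 kb and 3 at 20 kb. Bins whose total lay under 0.1 of the arm median were left out, which removed 20 of 2996 bins at 40 kb and 106 of 11816 bins at 10 kb.

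Coverage of a bin was the sum of its observed contacts with other chromosomes over the sum of their expected counts. The end of the raised X tip was the split of the first 2 Mb into 2 levels with the least squared error. Contact decay was the slope of log10 observed over expected on log10 distance. For all other measurements within an arm, the expected count was multiplied by the arm mean at each distance, here called the distance-corrected expectation. Insulation was the log2 ratio of observed contacts to this expectation across each bin edge, in windows of 100 kb and bins of 10 kb. A boundary was a local minimum of insulation, at least 50 kb from another, with a prominence of at least 0.3. Contacts inside domains were set against those across 1 boundary at distances of 50 to 200 kb, with 100 circular shifts of the boundaries as the baseline for placement. Boundaries and contacts came from the same map.

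Classes of bins were taken from the sign of the first eigenvector of the correlation matrix of each arm at 40 kb, and numbered by their number of bins. Compartment strength was the contact of pairs in the same class over pairs in different classes, over 1 Mb apart, for the 20% of bins at each extreme. Contacts between arms were observed over expected counts, relative to all pairs of bins on different chromosomes. Contacts between arm ends covered the 2 Mb at each end and were taken relative to the same pair of arms.

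Long-range contacts were bin pairs over 1 Mb apart on an arm with at least 10 observed contacts, at least 3 times the expectation, and a Benjamini-Hochberg adjusted upper-tail Poisson p under 0.05. Hits within 3 bins of each other were joined. The rule fixed beforehand asked for 40 kb bins where the median pair at 20 kb held fewer than 10 counts, which was the case. These p-values cover counting error only.

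Unless stated otherwise, intervals are 95% intervals from 1000 draws of 1 Mb blocks along the arms. They cover variation between loci of 1 map and not between embryo collections. For the X tip ratio the 7 bins of the tip were drawn singly and the rest of X in 1 Mb blocks, with the split held fixed. Lists of regions to name were fixed by rule before the data were examined. They were the 5 longest domains and the longest of each arm, the 10 boundaries of highest prominence and the highest of each arm, the 20 long-range contacts of highest ratio and the highest of each arm, the 3 bins of each arm with highest and lowest coverage, the X tip and the arm ends. Of the coverage bins the text names only some, and 4 of the contacts are given by 1 anchor. The planned measurement on gene lists was not run, because the gene table at hand belongs to another build than dm3, and regions are therefore named by position alone.

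The programs were tested on simulated maps with known answers. Of 96 planted boundaries with a fold of 1.5, 91.7% were recovered, and none was called on 2298 bins without boundaries. Of 200 planted long-range pairs with a fold of 4, 96.5% were recovered with 0 false calls. These maps were Poisson draws around the distance-corrected expectation of 2L or 3R, without the contrast of classes and not at the depth of X. The criteria leave almost no room for false calls in such draws. They test the programs and give no error rate for the deposited map. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Alternatives covered bin size, the filter, the use of the expected counts, windows, thresholds and thinning of the counts.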

Results

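The deposited map describes chromosome contacts in wild-type male embryos of Drosophila melanogaster late in embryogenesis, 16 to 18 h after egg laying. Its 2 replicates were available as 1 map of 50391732 contacts. The map covered the arms 2L, 2R, 3L, 3R and X and the small chromosome 4, in dm3 coordinates. The series concerns domains as units of chromosome folding, and with 1 group the comparisons lie between parts of the map. No value below has a replicate error.

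Most contacts joined loci of the same arm. Contacts within an arm made up 61.9% of the total, those between the arms of a chromosome 10.1%, and those between chromosomes 28.0%. The exact binomial 95% intervals of these shares extended by at most 0.0134 percentage points either side, which covers counting error only.

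The X, present once in males beside paired autosomes, had lower coverage than every autosomal arm. Median coverage against other chromosomes was 0.648 on X, compared with 0.976 on 2L, 1.00 on 2R, 0.978 on 3L and 0.973 on 3R. Chromosome 4 had the highest median, 1.58. X coverage over the autosomal median was 0.664 (95% interval 0.647 to 0.676). Copy numbers alone would give 0.590 here, since partners of autosomal bins include the single X. With partners on chromosomes 2 and 3 only, an alternative chosen after seeing the data, the ratio was 0.576 (0.565 to 0.589) and copy numbers alone would give 0.5.

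The tip of X departed from the rest of the arm. The genotype carries a duplication of X material on the Y marked by yellow, a pigmentation gene. Coverage was raised over the first 280 kb of X, at a median of 1.6 over 7 bins, and then fell to the level of the rest of the arm, 0.648. The ratio was 2.47 (2.22 to 2.60), an interval that holds the split fixed and treats neighbouring bins of the tip as independent. The 3 highest bins of X all lay in this tip, starting at positions 40001, 80001 and 160001, with coverages of 1.70, 1.62 and 1.67. The telomere-side ends of the autosomal arms were raised as well, at medians of 1.25 to 1.37 over the same distances. No step was fitted on them. Between the bins at 240 and 280 kb from the end, X fell from 1.23 to 0.747, while the autosomal ends stayed at 1.18 or above. From 280 kb to 1 Mb, X lay at 0.674 and the autosomal ends at 0.994 to 1.09. The place of the step depended on the setting, at 320 kb with 160 kb bins, 360 kb with observed counts alone and 240 kb from contacts over 2 Mb away on X in 10 kb bins. In the last of these the tip lay at 1.26 times the stretch from 240 kb to 2 Mb, and not the whole rest of X. That stretch itself lay at 1.15 times the distance-corrected expectation, so 1.26 is not comparable with 2.47.

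**Figure D1:**
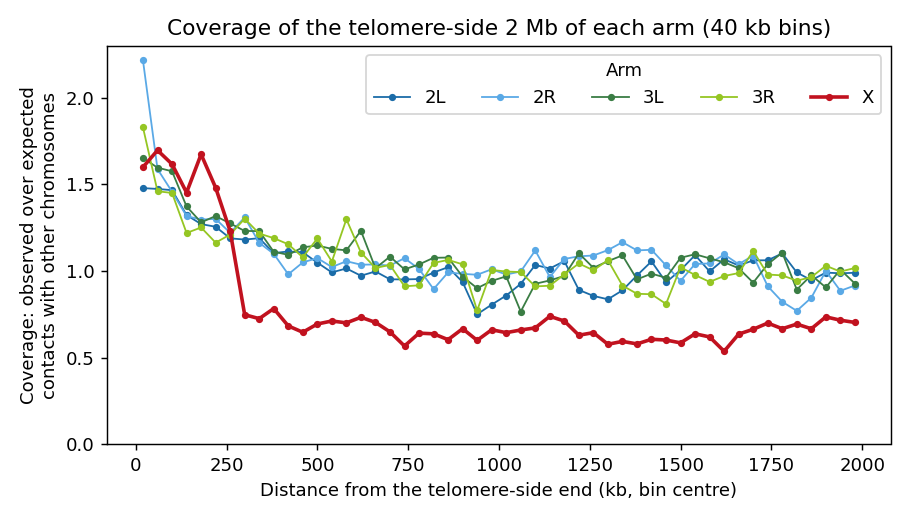
Coverage against other chromosomes (observed over expected contacts, y axis) by distance from the telomere-side end in kb (x axis) for the 5 large arms, 1 point per 40 kb bin. X had a median of 1.6 over its first 280 kb and 0.674 from there to 1 Mb, where the autosomal ends lay at 0.994 to 1.09.

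The bins of highest coverage on 2L, 2R and 3L lay toward the centromere side of each arm. The highest bin of 2L, from 20160001 to 20200000, reached 24.4 on 1220 contacts, and the highest of 2R, from 160001 to 200000, reached 5.29. On 3L the highest bin started at 23480001 with 2.95. On 3R it was the last bin, from 27880001, with 1.83 at the telomere-side end. The highest bins of 2L, 2R and 3L held 1220, 2709 and 2481 contacts with other chromosomes. These were fewer than in any of the 3 lowest bins of the same arm, so the high coverage there rests on low expected counts. Chromosome 4 was the most even arm among these extremes, with bins from 1.34 to 1.92. The lowest bins of the 4 autosomal arms lay between 0.685 and 0.762, and the lowest of X, from 19920001 to 19960000, at 0.476.

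Contacts within X fell below the autosomal level at every distance, and most at short distances. X over the mean of the autosomal arms was 0.393 (0.364 to 0.424) at 20 to 100 kb and 0.449 (0.405 to 0.494) at 100 kb to 1 Mb. It was 0.541 (0.519 to 0.563) at 1 to 5 Mb and 0.645 (0.592 to 0.699) over 5 Mb. The intervals of the shortest and the longest class did not overlap. With 1 X beside 2 copies of each autosome, copy numbers alone would give 0.5 if contacts between homologs are left aside. The classes under 1 Mb lay below 0.5 and those over 1 Mb above it. With observed counts alone the value at 1 to 5 Mb was 0.503 (0.475 to 0.532), an interval that includes 0.5.

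Contact frequency decayed less steeply on X than on the average autosomal arm. Between 20 and 200 kb the slope was -0.940 (-0.978 to -0.901) on X and -0.995 on average over the autosomal arms, which ranged from -1.02 on 2R to -0.961 on 2L. Between 200 kb and 2 Mb the slope was -0.800 (-0.860 to -0.743) on X and -0.870 on average over the autosomal arms, from -0.888 on 2L to -0.823 on 2R. X minus the autosomal mean was 0.0556 (0.0140 to 0.10) over the shorter range and 0.0693 (0.00332 to 0.136) over the longer one. The X slope lay within the interval of the nearest autosomal arm in both ranges, 2L (-1.01 to -0.902) over the shorter and 2R (-0.881 to -0.768) over the longer. With 1 X arm no test of these differences was possible.

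**Figure D2:**
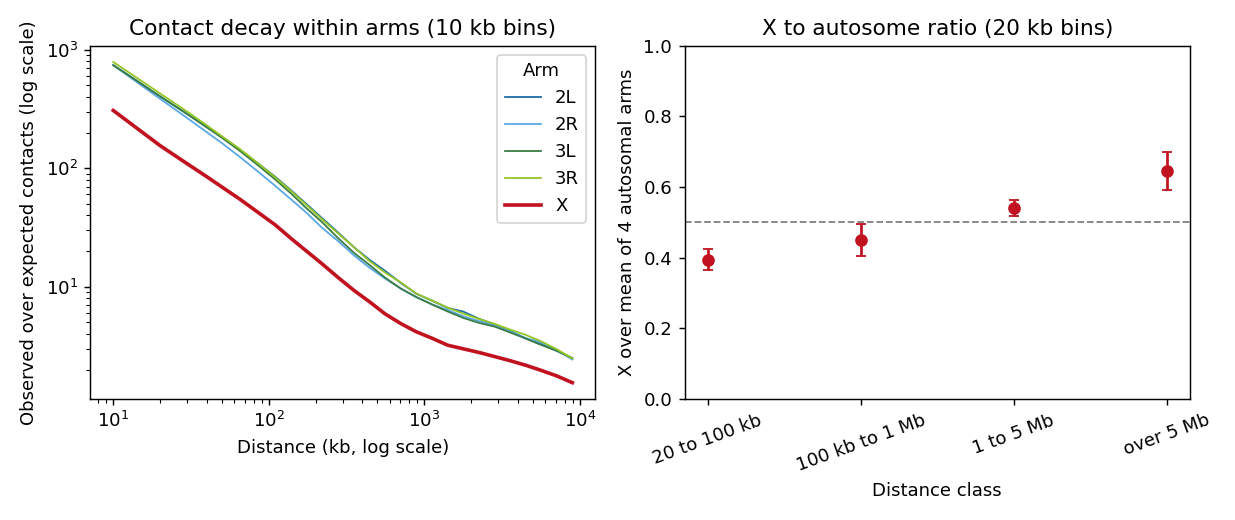
Left, observed over expected contacts (log scale) by distance in kb (log scale) for each of the 5 large arms in 10 kb bins; right, X over the mean of the 4 autosomal arms by distance class, with 95% intervals from 1 Mb blocks and a dashed line at 0.5. The ratio rose from 0.393 at 20 to 100 kb to 0.645 over 5 Mb.

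All 5 large arms were divided into domains of similar length. In total 586 boundaries were called, 108 on 2L, 111 on 2R, 116 on 3L, 138 on 3R and 113 on X. The median domain was 180 kb long, with arm medians from 170 kb on 2R to 190 kb on 2L, 3L and 3R, and 180 kb on X. X had 5.04 boundaries per Mb and the autosomal arms 4.91, a difference of 0.135 with an interval that included 0 (-0.323 to 0.602). The number depended on the window, with 880 boundaries at 50 kb and 376 at 200 kb, and the median length moved to 120 and 280 kb.

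The boundary of highest prominence lay on X at 6.75 Mb, with a prominence of 3.92 on the log2 scale, followed by X at 15.60 Mb with 3.81. Next came 2R at 9.85 Mb with 3.57, 3R at 18.18 Mb with 3.56 and 16.94 Mb with 3.47, and 2L at 12.00 Mb with 3.38 and 10.20 Mb with 3.37. X at 8.98 Mb, 2R at 2.52 Mb and 3R at 13.99 Mb had prominences of 3.35, 3.35 and 3.33. The highest of 3L was at 15.50 Mb with 3.20. The median over all boundaries was 1.01.

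The longest domain, on X from 21180001 to 21890000, spanned 710 kb, but 49.3% of its bins passed the filter. On 3R a domain of 700 kb ran from 1480001 to 2180000, and its inner contacts lay at 1.53 times the distance-corrected expectation. A domain of 570 kb on 2R, from 15580001 to 16150000, reached 2.34. The longest of 2L, from 13840001 to 14360000, and of 3L, from 13480001 to 14000000, both spanned 520 kb and had values of 1.19 and 1.52.

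Loci of the same domain were in contact about 2 times as often as loci at equal distance across 1 boundary. The ratio was 2.12 (2.02 to 2.24) over all 5 arms, 2.13 (2.01 to 2.25) on the autosomal arms and 2.08 (1.82 to 2.31) on X. Shifted boundaries gave 0.934 to 1.06 in 100 shifts. With boundaries and contacts taken from separate parts of the counts the value stayed within the interval.

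Each arm separated into 2 classes of bins that met their own class more often. Compartment strength was 1.79 (1.75 to 1.83) over the 5 arms. Classes were taken from the same contacts, so a strength above 1 follows in part from how they were drawn. With classes and contacts from separate parts of the counts the strength was 1.78. X had the highest value, 2.09 (2.02 to 2.19), compared with 1.88 on 2L, 1.74 on 3R, 1.73 on 3L and 1.68 on 2R. The autosomal arms together had 1.76 (1.71 to 1.80). In every arm the classes differed in their boundaries. On X the class with fewer boundaries held 60.5% of bins, with 2.32 boundaries per Mb compared with 9.40 in the other class. On the autosomal arms the class with fewer boundaries held 37.2 to 46.7% of bins, with 1.03 to 1.51 boundaries per Mb compared with 7.62 to 7.88. The classes were not oriented by gene density.

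Between arms, with no correction for differences in coverage, chromosome 4 with the autosomal arms had the highest ratio and X with the autosomal arms the lowest. Relative to all pairs of bins on different chromosomes, chromosome 4 met the autosomal arms at 1.83 (1.75 to 2.00) and X at 1.06 (1.00 to 1.17). The arms of chromosome 2 met each other at 1.42 (1.35 to 1.5) and those of chromosome 3 at 1.37 (1.32 to 1.43). Arms of chromosome 2 met those of chromosome 3 at 1.22 (1.19 to 1.25), and X met the autosomal arms at 0.710 (0.690 to 0.733). The last 2 values changed sides under division by the product of bin totals, where they became 0.959 and 1.05. Chromosome 4 with X was then the highest of the 6 kinds at 1.42, and chromosome 2 with chromosome 3 the lowest. These totals also hold contacts within arms. Over all contacts X lay at 0.533 of the autosomal level, below its coverage ratio of 0.664. The divided values therefore do not give contacts at equal coverage.

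**Figure D3:**
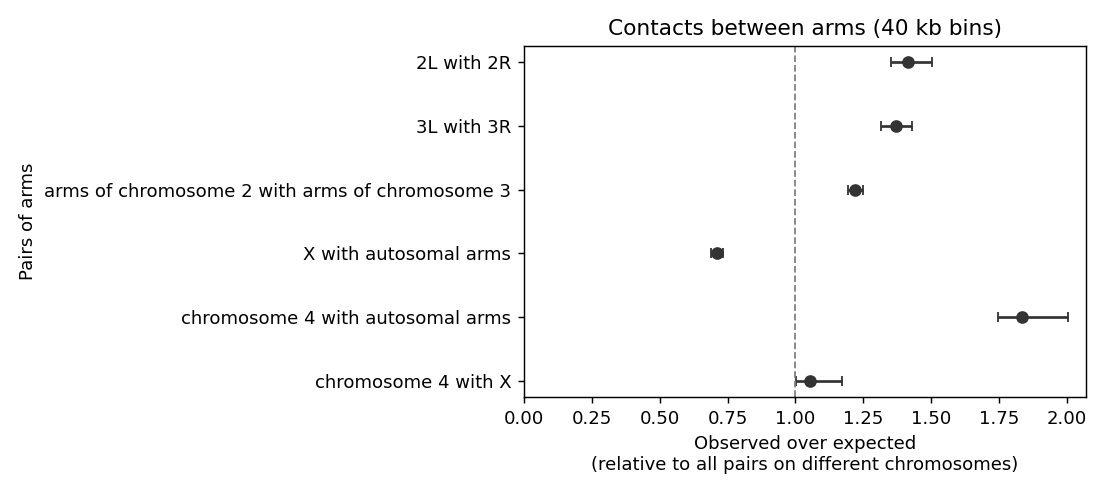
Observed over expected contacts between arms, relative to all pairs of bins on different chromosomes (x axis, dashed line at 1), for 6 kinds of arm pairs (y axis), with 95% intervals from 1 Mb blocks. Chromosome 4 with autosomal arms was highest at 1.83 and X with autosomal arms lowest at 0.710.

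Arm ends of the same kind met more often than the arms as a whole. Over the 8 pairs of large arms on different chromosomes, centromere-side ends met at a median of 1.5 (1.37 to 1.83) and telomere-side ends at 1.40 (1.17 to 1.65). Ends of different kinds met at 1.15 (1.03 to 1.3). All 8 pairs lay above 1 for each of these. The values were not corrected for coverage of the bins. Over the 280 kb at the telomere side, coverage was 1.29 to 1.41 times the rest of the arm on autosomal arms and 2.47 times on X. These 280 kb are only a part of the 2 Mb measured. Raised contact of end bins with all partners would lift ends of different kinds as well. In each of the 8 pairs, however, ends of different kinds met less often than either kind with itself. Raised contact with all partners as the only source is thus argued against, though the intervals of telomere-side and mixed ends overlapped. The share of each value that goes with coverage was not separated. The highest value for centromere-side ends on different chromosomes was 2.08 for 2R with 3L. Within a chromosome, the centromere-side ends met at 3.26 for 2L with 2R and 1.94 for 3L with 3R. Away from the ends, loci at matched distance from the centromere met at 1.01 (1.00 to 1.02) and loci at unmatched distance at 0.974 (0.956 to 0.998).

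Long-range contacts joined separate regions of the same arm over several Mb. At 40 kb, 2114 of 803697 bin pairs passed and formed 770 contacts, with a median distance of 5.14 Mb. X held 382 of them, 3R 120, 2L 113, 3L 87 and 2R 68. The ratio of X to the mean autosomal arm, 3.94, depended on the settings. It was 1.52 when contacts were called again at 2 times the expectation, 2.33 at 5 times and 2.09 with 0.5 of the counts. With 20 kb bins, chosen as an alternative after seeing the data, X held 321 and the autosomal arms 371.25 on average. With the autosomal arms also thinned to the X level, X held 222 and the autosomal arms 109 to 211. Most contacts joined 2 bins of the class with fewer boundaries, 339 of 382 on X, 83 of 113 on 2L, 46 of 68 on 2R, 63 of 87 on 3L and 103 of 120 on 3R. That class held 60.5% of bins on X and 37.2 to 46.7% on the autosomal arms. X therefore offered more such pairs, and the counts are not directly comparable between X and the autosomal arms.

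Among the 770 joined contacts, 52 reached 5 times the expectation or more, of which X held 20, 2L 11, 3L 10, 3R 6 and 2R 5. At 10 times or more, 2L held 7, 3L 5, 2R 4, and 3R and X 2 each. On 2R, bins starting at 4.68 and 10.88 Mb had 300 contacts, 40.4 times the expectation, and 4.56 and 17.88 Mb had 86 (10.1 times). On 3L, 12.96 and 18.68 Mb had 195 contacts (20.6 times), 12.84 and 20 Mb had 290 (13.7 times), and 6.64 and 9.28 Mb had 192 (15.6 times). On 3R, 19.36 and 24.48 Mb had 347 (19.7 times), and 0.96 and 7.84 Mb had 217 (18.0 times). On 2L, 6.36 and 9.44 Mb had 345 (15.2 times), and 2.08 and 10.92 Mb had 72 (27.2 times). Also on 2L, 13.32 and 19.6 Mb had 112 (16.3 times), 6.4 and 9.04 Mb 160 (11.4 times), and 0.92 and 2.68 Mb 173 (11.3 times). On X, 0.88 and 15.92 Mb had 42 contacts, 44 times an expectation of 0.954, and 5.32 and 17.48 Mb had 66 (15.6 times). The highest ratio of all, 70.6 on 773 contacts between 20.12 and 21.68 Mb of 2L, lay beside the bin with 25.0 times the median coverage of its arm. The same bin lay beside an anchor of the contact between 13.32 and 20.20 Mb of 2L (29.1 times). Anchors at 0.16 Mb of 2R and at 23.48 and 23.04 Mb of 3L had 5.27, 3.02 and 2.24 times the arm median.

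**Figure D4:**
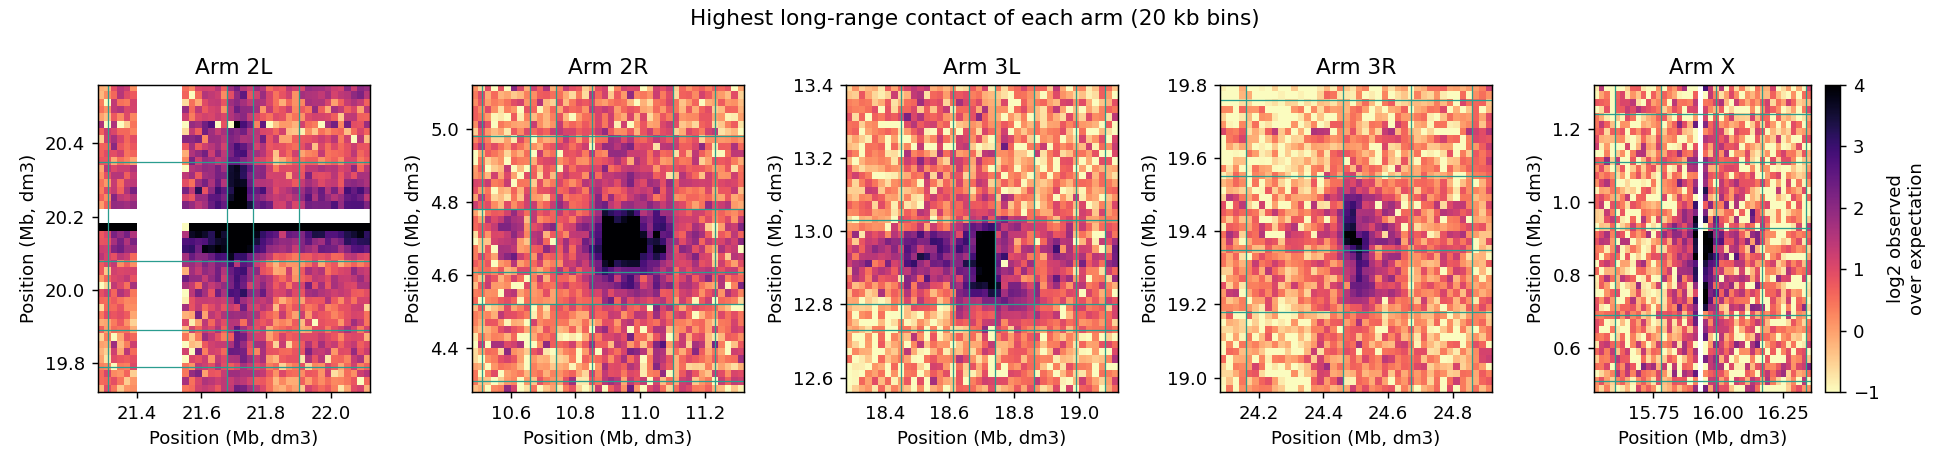
Observed contacts over the distance-corrected expectation (log2 colour scale, which saturates at 4) in 20 kb bins around the highest long-range contact of each of the 5 large arms, with both axes in Mb of dm3, domain boundaries as green lines and bins left out in white. The contacts of 2R and 3L lay mostly within a pair of domains, that of 3R crossed a boundary, and that of 2L lay on a stripe through the bin of highest coverage.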

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

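No paired analysis was possible because the map pools both replicates, and leaving out a replicate was not possible for the same reason. The gene list measurement was not run. Of 148 recomputed values, 99 stayed within the interval of the main value or within 1.5 times a count, 46 moved and 3 changed sides. The cause was not tested unless given. Alternatives named here as added were chosen after the data were seen. With observed counts alone, X coverage was 0.642, the X tip ratio 1.88, the X ratio at 1 to 5 Mb 0.503, the median domain 170 kb and the ratio of contacts inside to across domains 1.97. With 160 kb bins the tip ratio was 2.13. With partners on chromosomes 2 and 3 only (added), X coverage was 0.576. The median domain was 200 kb with 20 kb bins, 170 kb with 5 kb bins, and 160 and 230 kb with a prominence of 0.2 and 0.5. Windows of 50 and 200 kb gave 880 and 376 boundaries and medians of 120 and 280 kb, and the smaller window a ratio inside to across of 1.95. Compartment strength over all arms, on X and on autosomes was 1.65, 1.89 and 1.62 with 80 kb bins, and 1.24, 1.34 and 1.23 when all bins entered, which adds bins near the class border. Division by the product of bin totals gave 1.15 for 2L with 2R, 1.05 for 3L with 3R, 0.959 for chromosome 2 with 3, 1.05 for X with autosomes, 1.31 for chromosome 4 with autosomes and 1.42 with X. With ends of 1 Mb, centromere-side, telomere-side and mixed ends met at 2.02, 1.84 and 1.45; with 4 Mb the centromere-side and mixed ends met at 1.20 and 1.02. Long-range contacts called and joined again numbered 2781 at 2 times the expectation (X 764, autosomal mean 504.25, ratio 1.52) and 57 at 5 times (21, 9 and 2.33), where fewer hits were joined. The ratio of X to the autosomal mean was 2.09 with thinned counts and 2.51 with autosomal arms thinned to the X level (added). With 20 kb bins (added) there were 1806 contacts, 371.25 per autosomal arm, and a ratio of 0.865. With 20 kb bins and thinned autosomal arms (added), X had 222, the autosomal mean was 160.25 and the ratio 1.39. At 20 kb the low counts limit which pairs can pass.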

Other observations

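Contacts between arms were also searched for single bin pairs above the margins of each pair of arms, a search chosen after the data were seen. Of 3469264 pairs of 40 kb bins, 282 passed the criteria used within arms, 154 between the arms of a chromosome and 128 between chromosomes. Between chromosomes, 115 of the 128 joined telomere-side regions, 1 joined centromere-side regions and 7 joined inner regions. Between the arms of a chromosome, 94 joined centromere-side regions, 51 telomere-side regions and 8 inner regions. The highest of all joined the first bin of 3L with the last bin of 3R, with 80 contacts, 27.5 times the expectation. Among the inner pairs 1 stood apart, from 11640001 on 3L and 24320001 on 3R, with 102 contacts at 19.2 times the expectation; the next highest had 11 contacts at 6.12 times. Sequence shared between bins was not examined.

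The 561 long-range contacts under 9.5 Mb were set against the domain pairs that held them, again after the data were seen. The domain pair met at a median of 1.24 times its neighbouring domain pairs, and boundaries shifted around the arm gave 1.13 to 1.21, with 0 of 100 shifts as high. For the 13 of the 20 strongest contacts that could be placed, the median was 2.89 and the shifts gave 1.40 to 2.71. The 52 contacts of 5 times or more had anchors in 73 domains or arm-end segments, of which 22 held anchors of at least 2 contacts.

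In the paragraphs that follow, the tests on counting noise on X, on one factor for all X contacts, on paired homologs and on a rise at every telomere end were chosen only after the result was seen. With 1 group in the map, no explanation was tested by a comparison of groups.

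The larger number of long-range contacts on X at 40 kb bins, 3.94 times the mean autosomal arm, fell to 1.52 times at 2 times the expectation, 2.09 with 0.5 of the counts, and at 20 kb bins 0.865 at full depth and 1.39 with thinned autosomal arms. Counting noise as the only source of the X contacts is argued against. The 264 X contacts called in a random 0.5 of the counts lay at 2.32 times the expectation (2.18 to 2.45) in the remaining counts. This does not address the excess of X over the autosomal arms, whose contacts lay at 2.84 times in the same test. Noise did raise the ratios of called contacts, from 2.32 to 3.99 on X and from 2.84 to 4.08 on the autosomal arms, and 60 of the 264 and 107 of 506 reached 3 times in the remaining counts. Adjustment of the expectation for the contrast of same-class and different-class pairs lowered X from 382 to 235 contacts and the mean autosomal arm from 97 to 67.25. Part of the contacts on X and on the autosomal arms thus went with this contrast, and X stayed at 3.49 times the mean autosomal arm. A finer adjustment with 10 classes, not the one planned, left 122 contacts on X and 34 on the mean autosomal arm, 3.59 times. The part that went with the contrast was thus larger under the finer classes. The class with fewer boundaries held more of the bins on X, so these counts are not directly comparable between arms. Lower depth on X explains a part at most: with the autosomal arms thinned to the X level they rose from 97 to 136.5 contacts per arm, which stayed below the 343 of X in the same run.

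The low contact of X at 20 to 100 kb, 0.393 of the autosomal level, was not produced by the expected counts of the authors, since observed counts alone gave 0.366. A single factor for all X contacts is argued against by the rise of 0.252 between the shortest and the longest distances. Contacts between paired autosomal homologs, counted as contacts within an arm, stay open as a candidate explanation. X coverage against chromosomes 2 and 3, where such contacts do not enter, was 0.576, but copy numbers alone give 0.5 there and the value was known when the test was chosen. Homologs were not separated in this map.

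The step in coverage at the tip of X was larger than a rise at every telomere end would give. X lay at 1.21 times the median of the 4 autosomal ends there, compared with 0.664 over the whole arms. A second copy of the tip on another chromosome may account for it, and the genotype names a duplication on the Y. Contacts within the tip at 20 to 100 kb were 2.49 times those of other X windows, above all 57 of them. These windows lay on X only, so a rise shared by telomere-side ends was not separated from this value. A tandem copy next to the first on X cannot be told apart from a copy on another chromosome. Contacts from the tip to the next 1 Mb, at 1.38 times other windows, lay within their spread (SD 0.371). Contacts from the tip to X over 5 Mb away were 1.5 times those of other windows, above all 57.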
